A study of Mus musculus with 8 samples.

How the data were processed

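Pancreata of mice at embryonic day 17 were digested to single cells, Neurog3-Cre lineage cells carrying the Tomato reporter were sorted, and RNA was extracted, per the labels' protocols. From each sample 2.315 ng of RNA, with an RNA integrity number above 8, was turned into amplified cDNA with the NuGEN Ovation V2 kit, and about 30 M single-end reads of 100 bp were sequenced on a HiSeq2000, per the labels' protocols. That kit amplifies cDNA from very little RNA, strand is not kept, and amplified copies are counted as reads.

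The deposited counts are whole numbers of reads per gene symbol, not normalized, in 1 file per library. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.1.0, Cufflinks 2.0.2 and DESeq were used with the mouse genome build mm9. The counting tool, the gene annotation, the treatment of reads that match several genes and the DESeq version are not given in the sources used here. The authors also deposited a table of their own comparison. Its mean signal per group is, per the file headers, a mean of normalized counts, and the deposited group means equal the means of the counts divided by median-ratio size factors computed here, with a largest relative deviation of 4.92e-15. The authors' fold change is the ratio of the KO mean to the Het mean, the authors' log2 fold change is its log2, and the authors' p-values and adjusted p-values stand beside them, per the file headers. Genes are named by the symbols in the files. No coordinates are given, because the reference annotation used here is of another build than the files.

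Each library was assigned to KO or Het from its labels, and replicate numbers are the library numbers in the sample titles. They are not shared between genotypes, and the labels give no batch. No 2 libraries held the same values. The closest pair differed by a chi-square of 18.2 per degree of freedom over its genes, and correlations of log2 CPM between libraries ran from 0.814 to 0.965. No column of per-sample values was left unmatched.

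Of 23284 genes, 18760 had a count in some library, and edgeR's filterByExpr (minimum count 10, minimum total count 15) kept 14116. Libraries were scaled by TMM factors, and CPM values use the scaled library sizes. KO was compared with Het by edgeR's quasi-likelihood F test, two-sided, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called at an adjusted p under 0.05. All log2 fold changes are KO over Het. The common dispersion was 0.181, and the median log2 fold change of all tested genes was 0.03. At totals of 10.35 M to 16.1 M counts, 1 CPM stands for about 10 counts or more in each library, and counting error is largest for named genes of low level such as B3gnt3, Cldn5 and Ghsr.

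The gene lists, the tests and the rule for naming genes were set before the data were examined. Lists covered islet hormones, beta-cell, alpha-cell and delta-cell markers, endocrine progenitor genes, islet transcription factors, secretory granule and exocytosis genes, stimulus-secretion coupling genes, genes usually silent in beta cells, S and G2/M genes, G1 regulators, apoptosis, unfolded protein response, neuronal, Notch pathway and immediate-early genes, and acinar, duct, mesenchyme, endothelial, leukocyte, erythroid and Schwann-cell or neural-crest markers. Of the listed genes only Map2 had no row under its symbol. Lists share some genes, such as Ins1 and G6pc2. The 22 lists with at least 3 tested genes were compared with all other genes by camera from limma on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move one way without comparing them with other genes, were run beside it. Shares of counts, the cell-cycle score and the log2 ratio of Ins1 to Ins2 were compared by exact permutation tests, two-sided, over 70 assignments.

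The rule named Neurod1; the 8 largest falls and 8 largest rises among called genes with a mean of at least 8 CPM and groups that do not overlap, leaving out unnamed gene models; all islet hormones; from every other list up to 3 called members with the smallest p, or the 1 with the smallest p where none was called; and Xist and Ddx3y as a check of library make-up. It gave 45 genes besides that pair, of which 1 is not reported here. Other members of the lists are named as examples chosen after their values were seen.

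Alternatives were median-ratio scaling, total counts, TMM without the hormones, DESeq2, limma-voom without and with sample quality weights, no filter on low counts, a filter of 2 CPM in 4 libraries, 1 surrogate variable from sva, an acinar covariate, a test against a fold of 1.5, and each library left out in turn. Covariates for mesenchyme markers and for Y-linked genes, a robust fit, a table without Rn45s, and KO replicate 8 left out together with the Y-linked covariate were chosen after seeing the data. The method was tested on counts simulated for KO against Het from the libraries' own means and sizes, over 13879 tested genes. It recovered 30 of 100 genes changed 2-fold and 91 of 100 changed 4-fold, with 10 false calls among 131, and camera called none of 50 lists of unchanged, independent genes. The changed genes were drawn from those with a mean of at least 8 CPM, and no simulated library was made to stand apart from its group. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15 and matplotlib 3.10.9.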

Results

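RNA was sequenced from 8 libraries of mouse pancreatic endocrine cells at embryonic day 17. The cells carried a Neurog3-Cre transgene, active in the precursors of all islet cell types, and a Cre-dependent Tomato reporter, and Tomato-positive cells were collected by flow cytometry. In 4 libraries both alleles of Neurod1, a basic helix-loop-helix transcription factor of endocrine and neuronal cells, were floxed (KO, replicates 8, 9, 17 and 24). In the other 4 libraries only a single allele was floxed (Het, replicates 6, 7, 13 and 19). The deposited gene counts summed to between 10.35 M and 16.1 M per library, over 15443 to 16538 detected genes. The ribosomal RNA gene Rn45s took between 0.902% and 5.54% of them. The labels do not say that replicates came from separate animals, so p-values here measure the spread between these libraries. The comparison asks what the loss of both Neurod1 alleles, against the loss of a single one, changed in the transcripts of these cells.

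Neurod1 itself was lower in every KO library than in every Het library. It stood at 14.8 ± 9.17 CPM (counts relative to the scaled library size; SD, n = 4) in KO and at 156 ± 36.5 CPM (SD, n = 4) in Het, a log2 fold change of −3.40 (SE 0.52, adjusted p = 0.0165, edgeR quasi-likelihood test). The KO libraries held 2.55, 12.9, 22.2 and 21.5 CPM in the order of their replicate numbers, and the lowest Het library held 133 CPM. These counts cover the whole gene and do not show which part of it the remaining KO reads came from. Leaving out KO replicate 9 or any 1 Het library raised the adjusted p to at most 0.0732, with fewer libraries in the fit, and the log2 fold change stayed between −3.68 and −3.06. With all 8 libraries and a covariate for Y-linked expression the adjusted p was 0.0725.

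Of 14116 genes tested, 96 were lower and 48 were higher in KO than in Het, and 101 of these 144 differed by 2-fold or more. The largest fall among the genes picked by the naming rule was that of Nnat, an imprinted gene for a small membrane protein of neurons and beta cells, from 2045 ± 284 to 71.2 ± 50.1 CPM (SD, n = 4 each). Its log2 fold change was −4.84 (SE 0.44, adjusted p = 0.00116). G6pc2, a glucose-6-phosphatase catalytic subunit of beta cells, fell from 484 ± 74.5 to 32.5 ± 7.88 CPM and had the smallest p of all genes tested (log2 fold change −3.89, SE 0.22, adjusted p = 5.71e-05). Other large falls were those of the glycosyltransferase gene B3gnt3 (log2 fold change −4.02), Ins1 (−3.64), Npy (−3.36), which encodes neuropeptide Y, and Cntfr (−2.85), a receptor subunit for ciliary neurotrophic factor. Among the rises, the collagen gene Col19a1 went from 2.55 ± 2.05 to 40.7 ± 15.1 CPM (log2 fold change 3.98, SE 0.78, adjusted p = 0.0440). The complement gene C6 (2.70), the chloride channel gene Cftr (2.23), Clstn2 (2.18), the noncoding RNA Snhg11 (1.98), Rgma (1.87), the complement regulator Cd55 (1.87) and the adaptor gene Skap1 (1.87) followed. Nnat, B3gnt3, G6pc2, Ins1, Npy and Skap1 stayed called with any 1 library left out. Cntfr and Snhg11 lost their calls without any 1 library other than KO replicate 8 (adjusted p up to 0.127 and 0.116), Col19a1 without KO replicates 9, 17 or 24 or Het replicates 7, 13 or 19 (up to 0.179), and Clstn2 without KO replicates 9, 17 or 24 or Het replicates 6, 7 or 13 (up to 0.164). C6 lost its call without KO replicates 17 or 24 or Het replicates 7, 13 or 19 (up to 0.0878), Cd55 without Het replicates 7 or 13 (up to 0.0547) and Rgma without Het replicate 13 (0.0501). With all 8 libraries, Cntfr, Snhg11, Col19a1 and Clstn2 also lost their calls with a covariate for acinar-cell markers (adjusted p from 0.0599 to 0.0831), Col19a1 and Clstn2 by limma-voom (0.0892 and 0.0563), Col19a1 with a robust fit (0.0889), and these 4 genes, C6 and Cd55 with a covariate for Y-linked expression (0.0784 to 0.173). In all 144 genes the KO and Het libraries did not overlap. This held for 8.03% of the genes tested, where chance gives 2.86%. Without KO replicate 8, whose make-up is given with the markers of other cell types, 285 genes were called, 143 of the 144 among them. Without any other single library 29 to 67 were called, DESeq2 called 585, and a covariate for Y-linked expression left 28, or 135 with KO replicate 8 also left out.

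**Figure D1:**
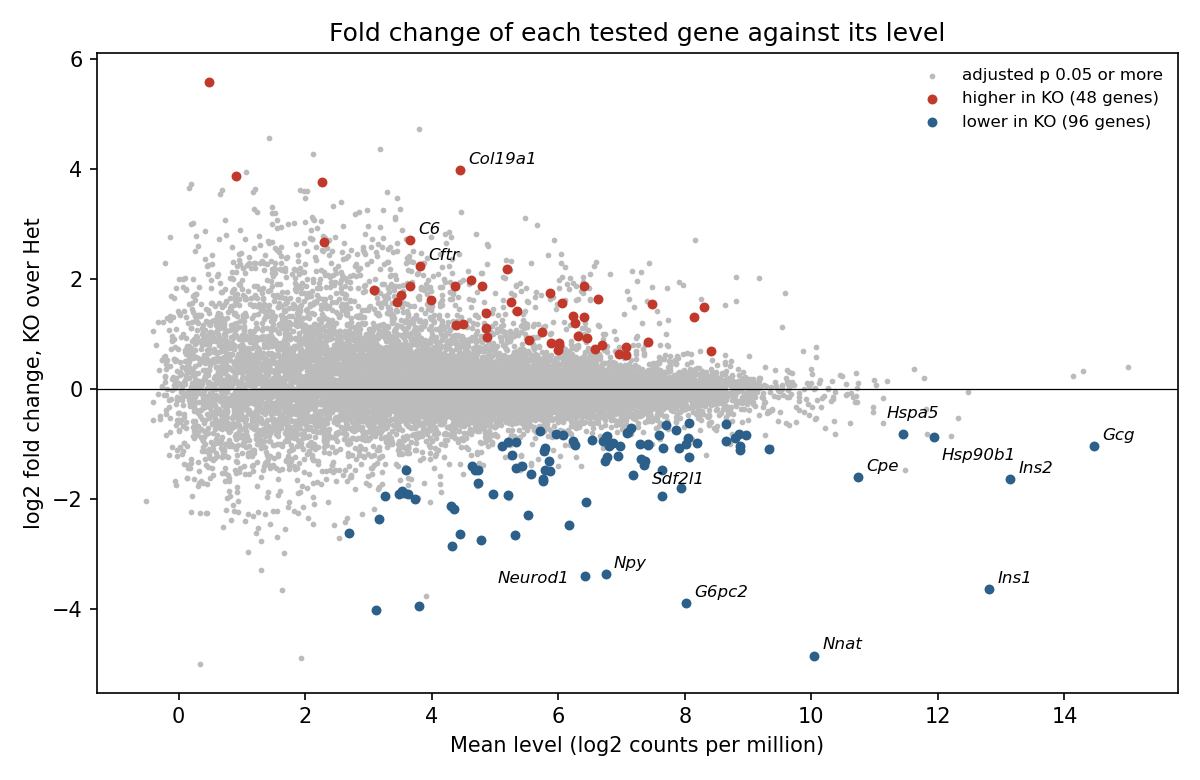
Log2 fold change of KO over Het for each of the 14116 genes tested, against its mean level in log2 CPM; coloured points have an adjusted p under 0.05. The 96 genes lower in KO include the abundant Nnat, Ins1, Ins2, Gcg and Cpe, and the mean CPM of a called gene has a median of 106 among the lower and 49.9 among the higher genes.

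Of the 8 islet hormone genes, 3 fell in KO and none rose over all genes tested, and 4, with Iapp, were lower when adjusted over the list alone. Ins1 fell from 13307 ± 7288 to 1069 ± 546 CPM (SD, n = 4 each; log2 fold change −3.64, SE 0.47, adjusted p = 0.00795). Ins2 fell less, from 13624 ± 2567 to 4403 ± 1491 CPM (log2 fold change −1.63, SE 0.26, adjusted p = 0.0195). The log2 ratio of Ins1 to Ins2 was −2.14 ± 0.36 in KO and −0.15 ± 0.52 in Het (SD, n = 4; exact permutation test over 70 assignments, two-sided, p = 0.0286, the smallest it can give). The pair are close paralogs, so how the authors' counting divided reads that match both is uncertain. Gcg, the glucagon gene, fell from 30589 ± 619 to 14870 ± 3994 CPM (log2 fold change −1.04, SE 0.21, adjusted p = 0.0440). Iapp, which encodes amylin, had a log2 fold change of −0.85 (SE 0.26, adjusted p = 0.200). Sst (−0.42), Ppy (0.16), Pyy (−0.05) and Ghrl (−0.17), which encode somatostatin, pancreatic polypeptide, peptide YY and ghrelin, did not pass the test, with adjusted p from 0.575 to 0.953. KO replicate 8 was the lowest library for 6 of the 8. Together the hormones took 3.41 ± 0.9998% of all counts in KO and 7.27 ± 0.98% in Het (SD, n = 4; exact permutation test, two-sided, p = 0.0286), and Ins1 with Ins2 took 0.557 ± 0.205% against 2.63 ± 0.86% (exact permutation p = 0.0286). Ins2 and Gcg each lost their call when KO replicate 9, KO replicate 17 or any 1 Het library was left out, at adjusted p up to 0.0771 and 0.143. With all 8 libraries Gcg also lost it by total counts (0.0559), with no filter on low counts (0.0523) and with the acinar (0.0652) and Y-linked (0.170) covariates, and Ins2 with the Y-linked covariate (0.0973).

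**Figure D2:**
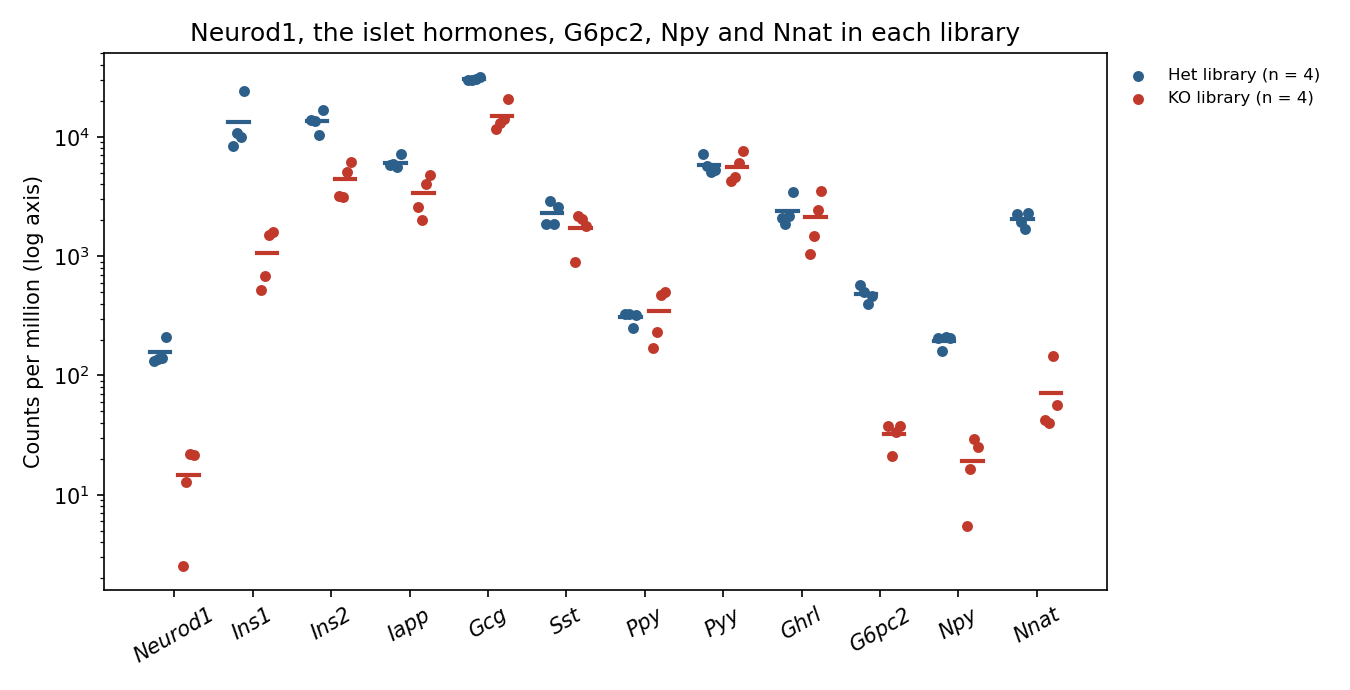
CPM on a log axis in each of the 4 Het (blue) and 4 KO (red) libraries for Neurod1, the 8 islet hormones, G6pc2, Npy and Nnat; horizontal bars are group means. Every KO library lies below every Het library for Neurod1, Ins1, Ins2, Iapp, Gcg, G6pc2, Npy and Nnat, and the groups overlap for Sst, Ppy, Pyy and Ghrl.

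Of 22 beta-cell markers, 4 fell (Ins1, Ins2, G6pc2 and Npy) and 18 did not pass the test over all genes. When adjusted over the list alone, 7 were lower, with Iapp, Mafa and Prlr, and 2 were higher, the GLP-1 receptor gene Glp1r and Spock2. The transcription factor gene Mafa had a log2 fold change of −2.61 (SE 0.55, adjusted p = 0.0578), and Pdx1 (−0.01), Nkx6-1 (0.24), the glucose transporter gene Slc2a2 (0.10) and Ucn3 (0.06) had adjusted p of 0.809 or more. The list was lower by a competitive test with a preset correlation (camera, adjusted p = 5.97e-05) but not with an estimated correlation (adjusted p = 0.461) or by fry, which tests whether members move one way (adjusted p = 0.0847). Of the 22, 12 were lowest in KO replicate 8, and without it the list's median went from −0.27 to −0.08 and its camera adjusted p was 0.0234. All 10 alpha-cell markers had a negative log2 fold change, with a median of −0.70. Gcg, the homeobox gene Irx1 (−1.40, SE 0.28, adjusted p = 0.0440) and the ETS factor gene Etv1 (−1.27, SE 0.19, adjusted p = 0.0165) fell, and 6 were lower when adjusted over the list alone. KO replicate 8 was the lowest library for 9 of the 10. Without it the list's median was −0.62, 5 markers were called lower and the camera adjusted p was 4.94e-05. With all 8 libraries the alpha-cell list moved down by fry (adjusted p = 0.0336), and camera gave an adjusted p of 1.14e-07, or an adjusted p of 0.271 with an estimated correlation. None of the 5 delta-cell markers passed the edgeR test over all genes (3 at an unadjusted p under 0.05, 1 called by DESeq2 and 1 by limma-voom with quality weights), and 1, the ghrelin receptor gene Ghsr (log2 fold change −1.97, adjusted p = 0.181), was lower when adjusted over the list alone. Of 29 islet transcription factors, 2 fell, which are the same Irx1 and Etv1, and 5, with Isl1, Mafa and Irx2, were lower when adjusted over the list alone. That list's median was −0.30, with camera adjusted p = 3.07e-05, or an adjusted p of 0.516 with an estimated correlation. KO replicate 8 was the lowest of the 8 libraries for 28 of these 29 factors, and without it the list's median was −0.06 and its camera adjusted p 0.437. Irx1 lost its call when any 1 library other than KO replicate 8 was left out (adjusted p up to 0.134), and Etv1 without KO replicate 17, KO replicate 24, Het replicate 7 or Het replicate 13 (up to 0.0719). With all 8 libraries Irx1 also lost it by total counts (0.0516), by limma-voom (0.0563) and with the acinar (0.0758) and Y-linked (0.204) covariates, and Etv1 with the Y-linked covariate (0.0806).

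Genes of the unfolded protein response, which encode chaperones and folding factors of the endoplasmic reticulum and its stress regulators, were lower in KO as a group. All 17 tested had a negative log2 fold change (median −0.82), 9 fell over all genes tested, none rose, and 10, with Herpud1, were lower when adjusted over the list alone. Manf, a secreted reticulum stress factor, fell from 324 ± 17.3 to 155 ± 17.2 CPM (SD, n = 4 each; log2 fold change −1.06, SE 0.12, adjusted p = 0.00550). Creld2 (−1.48, SE 0.18, adjusted p = 0.00670) and Sdf2l1 (−1.39, SE 0.19, adjusted p = 0.00974) fell more. Hspa5, the gene of the main reticulum chaperone BiP (−0.82, SE 0.15), Hsp90b1 (−0.88), Dnajb9, Dnajc3, Pdia4 and Pdia6 completed the 9. The stress regulators Atf4 (−0.09), Xbp1 (−0.09) and Ddit3 (−0.37) did not pass, with adjusted p of 0.793 or more. The list was lower by fry (adjusted p = 0.00147) and by camera (adjusted p = 6.67e-13), and had an adjusted p of 0.131 with an estimated correlation. Manf, Creld2 and Sdf2l1 kept their calls with any 1 library left out, and the same 9 members were lower without KO replicate 8, which was the lowest library for 9 of the 17. Without any other single library 3 to 8 members were called lower, with the fewest without Het replicate 7. With all 8 libraries there were 8 by total counts, 7 with the acinar covariate, 3 with the Y-linked covariate and 1, Creld2, against a fold of 1.5.

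**Figure D3:**
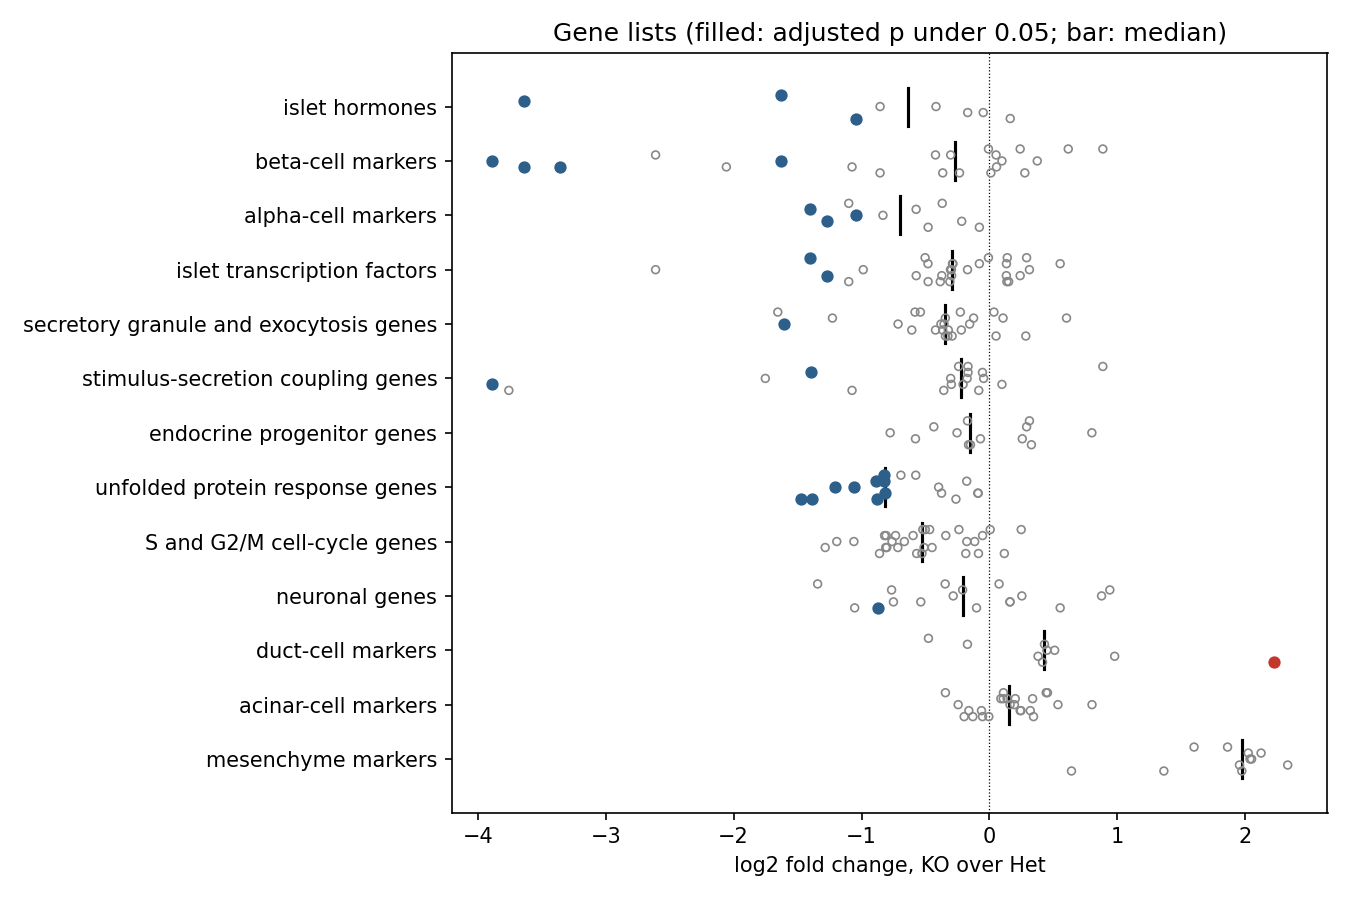
Log2 fold change of KO over Het for each tested member of 13 gene lists; filled points have an adjusted p under 0.05 over all genes and black bars are list medians. In the unfolded protein response list all 17 members lie below 0 and 9 are filled, while all 11 mesenchyme markers lie above 0 and none is filled.

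Few secretory genes were called, although 20 of 25 secretory granule and exocytosis genes and 16 of 18 stimulus-secretion coupling genes had a negative log2 fold change. At an unadjusted p under 0.05 there were 8 of the former, 7 of them lower, and 5 of the latter, 4 of them lower. DESeq2 called 3 and 5, and limma-voom with quality weights 4 and 5. Cpe, which encodes the prohormone-processing carboxypeptidase E, fell from 2564 ± 649 to 844 ± 138 CPM (SD, n = 4 each; log2 fold change −1.60, SE 0.21, adjusted p = 0.00795) and was the 1 of 25 secretory granule and exocytosis genes called, with Pcsk2 and Ptprn among 3 lower when adjusted over the list alone. Chga (−0.32), Pcsk1 (0.05), Pcsk2 (−0.71) and Snap25 (−0.15) were among the 24 that did not pass. The list had camera adjusted p = 3.07e-05, or an adjusted p of 0.464 with an estimated correlation, and 23 of its 25 genes were lowest in KO replicate 8. Of 18 stimulus-secretion coupling genes 2 fell, G6pc2 and the calcium channel gene Cacna1c (−1.40, SE 0.27, adjusted p = 0.0405), while 4, with Trpm5 and Gpr119, were lower and 1, Glp1r, higher when adjusted over the list alone. The ATP-sensitive potassium channel genes Abcc8 (−0.08) and Kcnj11 (−0.05) had adjusted p of 0.942 or more, and the list had camera adjusted p = 8.30e-05, or an adjusted p of 0.461 with an estimated correlation. KO replicate 8 was lowest for 14 of the 18. Without it the granule list's median went from −0.34 to −0.19 (camera adjusted p = 0.0330). The median of the coupling list went from −0.22 to −0.05 (camera adjusted p = 0.0269). Cacna1c lost its call when any 1 library other than KO replicate 8 was left out, at adjusted p up to 0.146, and with the acinar (0.0702) or Y-linked (0.176) covariate.

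None of the 30 S and G2/M cell-cycle genes passed the edgeR test, over all genes or adjusted over the list alone, although 27 had a negative log2 fold change (median −0.52). At an unadjusted p under 0.05 there were 8, all lower, DESeq2 called 1, and limma-voom with quality weights called 8, all lower. The member with the smallest p was E2f8 (−1.28, SE 0.37, adjusted p = 0.172). The list was called by camera (adjusted p = 8.89e-08) but had an adjusted p of 0.461 with an estimated correlation and of 0.229 by fry. The mean log2 CPM of the 30 genes was 4.09 ± 0.61 in KO and 4.70 ± 0.25 in Het (SD, n = 4; exact permutation test, two-sided, p = 0.143). KO replicate 8, at 4.93, was above every Het library, and the other KO libraries lay at 4.15, 3.73 and 3.56, below the lowest Het library at 4.33. Without KO replicate 8 the difference was −0.89 (exact permutation p = 0.0286, the smallest that 35 assignments give), the list's median was −0.97, and Ccnb2, Mcm3 and Rrm2 were called lower. Among 14 G1 regulators edgeR called none (4 at an unadjusted p under 0.05, 1 by DESeq2, 1 by limma-voom with quality weights; camera adjusted p = 0.706), with the smallest p for the cyclin D2 gene Ccnd2 (−0.9998, SE 0.31, adjusted p = 0.210), which was called without KO replicate 8 (−1.36, adjusted p = 0.0119). Of 14 apoptosis genes and 13 endocrine progenitor genes edgeR and DESeq2 called none, with 2 and 1 at an unadjusted p under 0.05 and camera adjusted p of 0.611 and 0.369. They had the smallest p for Trp53inp1 (0.56, adjusted p = 0.223) and Sox4 (0.80, adjusted p = 0.199). Both were called higher without KO replicate 8, at adjusted p = 0.0199 and 0.0183, and by limma-voom with quality weights. Neurog3, the marker of endocrine precursors, had a log2 fold change of 0.29 (SE 0.41, adjusted p = 0.824). Of 13 Notch pathway genes edgeR and DESeq2 called none (1 at an unadjusted p under 0.05; camera adjusted p = 0.215), with the smallest p for Lfng (1.45, adjusted p = 0.225). Of 17 neuronal genes 1 fell, the synaptophysin gene Syp (−0.87, SE 0.16, adjusted p = 0.0405), and 2, with Nefm, were lower when adjusted over the list alone. That list had camera adjusted p = 0.0293, or an adjusted p of 0.465 with an estimated correlation, and camera adjusted p of 0.571 without KO replicate 8, lowest for 12 of the 17, and of 0.0681 without Het replicate 13. Syp lost its call when any 1 library other than KO replicate 8 was left out, at adjusted p up to 0.120, and with the acinar (0.0739) or Y-linked (0.176) covariate.

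Among markers of other pancreatic cells, all 11 mesenchyme markers tested were highest in KO replicate 8, by a median of 20.8-fold over the median of the other libraries. The collagen gene Col1a2 stood there at 2552 CPM, against 65.2 to 298 CPM in the other 7. EdgeR called none (2 at an unadjusted p under 0.05, 1 by DESeq2; median log2 fold change 1.97; Pdgfrb 2.05, SE 0.71, adjusted p = 0.267), and the median was −0.73 without KO replicate 8. Camera gave the list an adjusted p of 0.153, and of 0.0238, 0.0268 and 0.0477 without KO replicate 17, KO replicate 24 and Het replicate 7. Leukocyte markers were 9.68-fold over the others in KO replicate 8 by median, and KO replicate 9 was also high (mean log2 CPM 5.35 and 4.89, against 2.67 and 1.35 in the remaining KO libraries). EdgeR called none of the 9 over all genes (4 at an unadjusted p under 0.05, 2 by DESeq2; C1qb 2.89, adjusted p = 0.119), and C1qb and Csf1r, 2 genes, were higher when adjusted over the list alone. Of the 15 genes usually silent in beta cells, led by Zfp36l1 (1.87, adjusted p = 0.227), and the 15 immediate-early and dissociation genes, led by Zfp36 (1.20, adjusted p = 0.338), edgeR and DESeq2 called none, with 4 and 1 at an unadjusted p under 0.05. Of the former, limma-voom with quality weights called 1, Oat, lower. KO replicate 8 was highest for 13 and 11 of them. Camera called these last 3 lists higher (adjusted p = 0.0170, 0.0293 and 0.0272), with adjusted p of 0.516, 0.631 and 0.631 with an estimated correlation and of 0.211, 0.783 and 0.361 by camera without KO replicate 8. The 3 calls were lost also without Het replicate 13 (0.0681, 0.0681 and 0.539). The leukocyte call was lost without KO replicate 9 (0.0838), that of the genes usually silent in beta cells without KO replicate 9 (0.0533) or Het replicate 19 (0.239), and that of the immediate-early genes without KO replicate 17 (0.0517) or 24 (0.0736). Duct-cell markers had a higher mean log2 CPM in every KO library (5.56 to 5.77) than in every Het library (5.05 to 5.39) and were higher by fry (adjusted p = 0.0157). Camera gave the list an adjusted p of 0.0192, or an adjusted p of 0.271 with an estimated correlation, and camera adjusted p = 0.0501 without Het replicate 13. Cftr was the 1 member of 9 called, also when adjusted over the list alone. Its call was lost without KO replicates 9, 17 or 24 or Het replicates 6, 13 or 19, at adjusted p up to 0.164, by limma-voom (0.0674) and with the Y-linked covariate (0.126). Of 7 endothelial markers, the tight-junction gene Cldn5 rose from 0.204 ± 0.139 to 3.22 ± 0.48 CPM (log2 fold change 3.88, SE 0.68, adjusted p = 0.0311), and lost its call when any 1 library other than KO replicate 8 was left out (up to 0.117), by limma-voom (0.0696), with no filter on low counts (0.0547) and with the acinar (0.0608) or Y-linked (0.116) covariate. It was also the 1 member higher when adjusted over the list alone. The list had camera adjusted p = 0.0746, and of 0.000850 to 0.0416 without KO replicates 17 or 24 or Het replicates 6, 7 or 19. Acinar-cell markers took 3.32 ± 2.12% of counts in KO and 2.74 ± 1.27% in Het (SD, n = 4; exact permutation test, two-sided, p = 0.686), and edgeR and DESeq2 called none of 24, with 0 at an unadjusted p under 0.05 (Cela1 0.44, adjusted p = 0.691; camera adjusted p = 0.669, and 0.0283 without Het replicate 6). The difference in share was −0.472 without KO replicate 9 (exact permutation p = 0.657). Of 5 Schwann-cell or neural-crest markers edgeR and DESeq2 called none, with 0 at an unadjusted p under 0.05 (Sox10 −1.06, adjusted p = 0.578; camera adjusted p = 0.437, and 0.0347 without Het replicate 19). Of the erythroid markers only Alas2 had enough counts to be tested (−0.13, adjusted p = 0.921). The globin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 had 0 counts over all libraries. How reads that match several genes were treated is not given, so these zeros do not show that red cells were absent. Xist stood at 5336 to 6037 CPM in KO replicate 17 and Het replicates 6, 13 and 19 and at 9.18 to 30.8 CPM in the other 4. The Y-linked Ddx3y stood at 88.4 to 146 CPM in those 4 and at 0.0883 CPM or less in the former, so that 3 of 4 KO and 1 of 4 Het libraries had Y-linked transcripts.

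**Figure D4:**
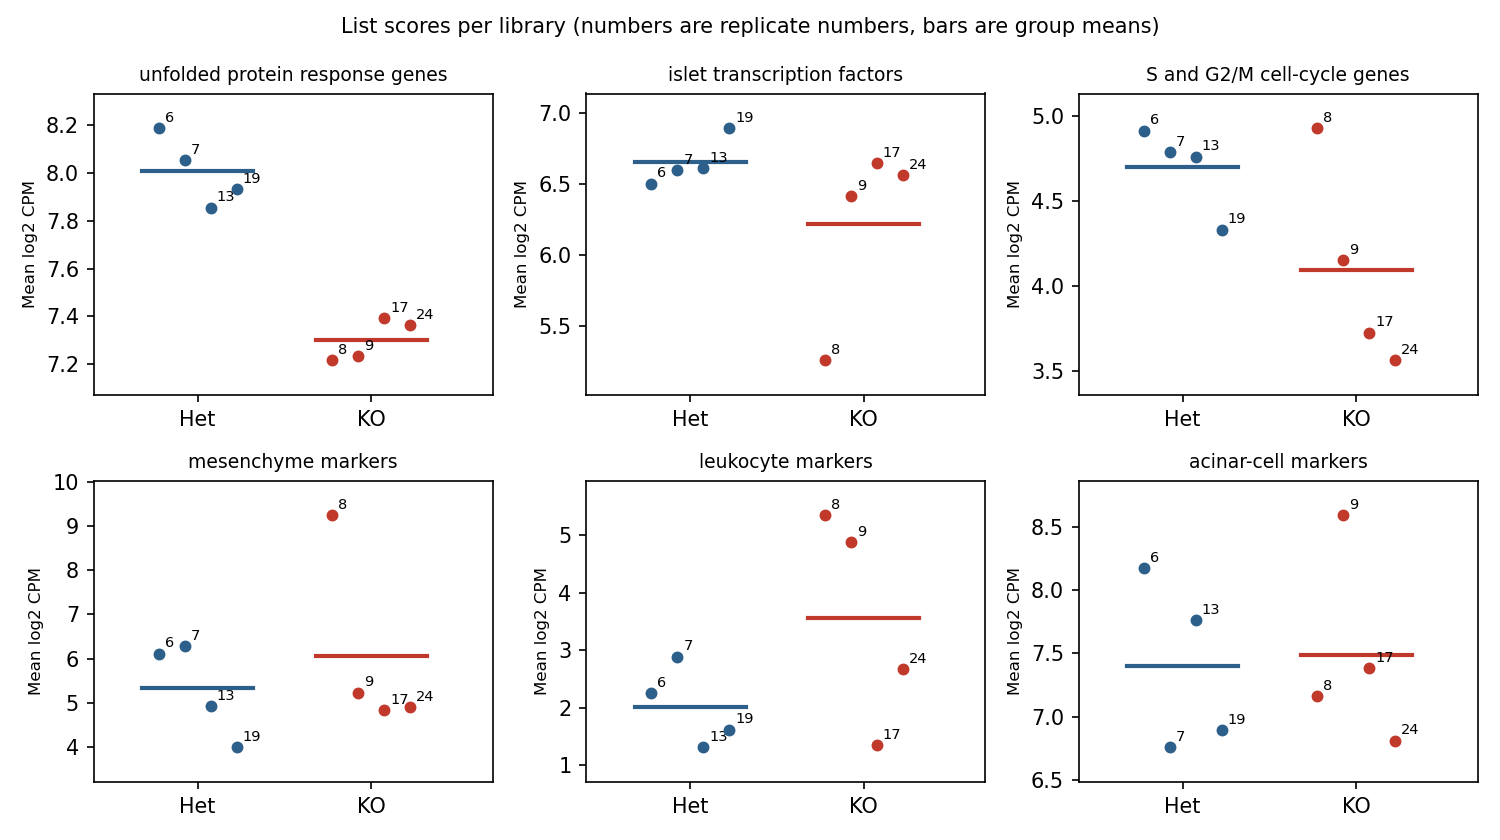
Mean log2 CPM of 6 gene lists in each Het (blue) and KO (red) library, with replicate numbers beside the points and group means as bars. All 4 KO libraries lie below all 4 Het libraries for the unfolded protein response genes, and KO replicate 8 stands at 9.24 for the mesenchyme markers, with the other libraries between 3.99 and 6.28.

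Camera with its preset correlation called 13 of the 22 lists. With an estimated correlation it called 0, with 3 lists at an unadjusted p under 0.05, and fry called 3, those of alpha-cell markers, unfolded protein response genes and duct-cell markers. Other divisions of the same 8 libraries into groups of 4 gave up to 15 lists by camera, so the counts of members carry the description of each list here.

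The authors' deposited table of the same comparison held 184 genes at an adjusted p under 0.05, of which 131 were lower and 53 higher in KO. It shared 114 genes with the 144 called here, all 114 in the same direction. With log2 fold changes of −3.89 and −4.85, G6pc2 and Nnat were among the genes lower in the authors' deposited table. The authors' deposited table gave Iapp an adjusted p of 0.0191, where the edgeR test gave 0.200.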

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

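All tests of explanations in this part, and the counts over other groupings of the libraries, were chosen or written down after the results were seen.

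In 16 of 148 groups of 4 libraries examined, 1 library lay far from the other 3 by Dixon's test of the gap over the group's whole range, where chance gives about 1 in 20 groups, or 7.4. KO replicate 8 was that library in 8 of the 16. Its mean log2 CPM was 6.84 for alpha-cell markers, against 7.61 to 7.76 in the other KO libraries (gap 0.831 of the range), 5.26 for islet transcription factors, against 6.42 to 6.65 (0.834), and 3.60 for neuronal genes, against 4.24 to 4.30 (0.910). For mesenchyme markers it was 9.24, against 4.83 to 5.23 (0.909), and these took 1.23% of its counts, against 0.0555 to 0.0729% (0.985). KO replicate 8 also stood apart for Sox4, at 25.2 CPM against 48.5 to 52.8 (0.845), Sdf2l1, at 64.8 CPM against 97.7 to 101 (0.918), and Pdgfrb, at 73.8 CPM against 6.29 to 15.6 (0.863).

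Het replicate 19 was apart from the other Het libraries for secretory granule and exocytosis genes (mean log2 CPM 8.23 against 7.90 to 7.93, gap 0.907), Schwann-cell and neural-crest markers (1.32 against 2.65 to 2.66, 0.993), Neurod1 (210 CPM against 133 to 141, 0.896) and Ins1 (24136 CPM against 8350 to 10726, 0.849). Nnat stood at 146 CPM in KO replicate 17, against 40.0 to 56.8 CPM in the other KO libraries (0.841). Notch pathway genes had a mean log2 CPM of 3.45 in KO replicate 24, against 3.66 to 3.68 (0.888). Npy stood at 161 CPM in Het replicate 7, against 206 to 210 CPM (0.919), and Ppy at 249 CPM in Het replicate 13, against 324 to 330 CPM (0.921).

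Mesenchyme markers were high in KO replicate 8, where Col3a1 stood at 3276 CPM against 82.2 to 393 CPM elsewhere and Sparc at 2208 CPM against 99.6 to 366. A rise of these genes by loss of Neurod1 is argued against by the median log2 fold change of −0.73 without KO replicate 8 (SD 0.64), with 1 of 11 markers above 0. A common scaling of all markers from outside the lineage is argued against by the acinar-cell markers, whose median log2 ratio in KO replicate 8 to the other libraries was −0.37 (SD 0.75). Mesenchymal cells in that pool stay open as a candidate source and were not tested, since the height of these 11 markers there, by a median of 20.8-fold over the other libraries, is the pattern itself. Leukocyte markers were also high there, by a median of 9.68-fold, with 6 of 9 highest in that library. Islet transcription factors were lowest there for 28 of 29. Both go with cells from outside the lineage but do not name their type. Schwann-cell and neural-crest markers were not raised (0.404-fold). Sorting for Tomato in the Neurog3-Cre lineage is meant to remove unlabelled cells. Yet acinar-cell markers took from 1.53% (Het replicate 7) to 6.45% (KO replicate 9) of the counts of a library. The sort therefore does not speak against cells from outside the lineage. Of the 11 markers, 9 stood at 8 CPM or more in the median of the other libraries and 1, Pdgfra, is in another list.

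Unfolded protein response genes were lower in KO, with a median log2 fold change of −0.82 (SD 0.43). Foreign RNA in KO replicate 8 as the whole cause is argued against by the median of −0.81 (SD 0.40) without that library, with 9 called. Unequal numbers of libraries with Y-linked transcripts are argued against by the median of −0.84 (SD 0.44) with a Y-linked covariate, under which 3 members stayed called, as SEs of the 144 called genes grew by a median factor of 1.18. A lower hormone load on the endoplasmic reticulum in KO cells may account for some or all of the fall. With the hormone share of counts in a linear fit, the mean log2 CPM of the 17 genes was lower in KO by 0.62 (SE 0.23, 95% interval of the difference −1.20 to −0.04), and the common slope within genotypes was 0.022 per percentage point (SE 0.053), where 0.182 would give the whole difference of −0.70. The difference stayed negative (−0.77 to −0.45) with any 1 library left out, but its 95% interval lay below 0 in only 1 of those 8 fits, and the hormone shares of the groups do not overlap (2.48 to 4.70% in KO, 6.53 to 8.68% in Het). A lower hormone load therefore cannot be told apart from a direct effect of the genotype. Nor can either be told apart from a changed mix of cell types in the sorted pools, such as a smaller share of beta cells, which was not tested. A biological cause stays a hypothesis.

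Ins1 fell by 3.64 on the log2 scale. The other 21 beta-cell markers had a median log2 fold change of −0.23 (SD 1.31). As far as they follow the share of beta cells, this argues against a smaller share as the whole cause. They were split, with G6pc2 (−3.89) and Npy (−3.36) falling about as far as Ins1, and Pdx1 (−0.01) and Slc2a2 (0.10) near 0. Whether markers with little change were confined to beta cells in these libraries was not tested. Reads moved from Ins1 to Ins2 as the whole cause are argued against by the share of counts of Ins1 with Ins2, which such a move would leave unchanged and which was lower by 2.07 percentage points in KO (0.557 ± 0.205% against 2.63 ± 0.86%, SD, n = 4). Whether reads shared between Ins1 and Ins2 add to the larger fall of Ins1, a difference of −1.99 in their log2 ratio, cannot be told apart from a real difference, since the treatment of such reads is not given in the sources used here. A smaller share of beta cells as part of the cause, or a change in the maturity of these cells, may remain and was not tested.

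Of the 35 ways to divide the 8 libraries into groups of 4, only 1, the division by genotype, gave as many called genes (144, the highest other giving 5). The same held for the larger direction (96 against 4) and the smaller one (48 against 1). A share of 1 in 35 is the smallest that 35 divisions can give, so chance is unlikely for these counts but not excluded. The division by genotype alone also gave as many lists by fry (3 against 1). It alone gave as small a fry p for the unfolded protein response genes (−log10 p 4.17 against 1.08). That list was picked after the results were seen and had the smallest fry p of all lists. The best list of each other division was not compared, so chance is not excluded for either. As many lists by camera with the preset correlation came from 8 of the 35 divisions (13 lists for the division by genotype, 15 for the highest other), so chance cannot be excluded for that number. All 8 put KO replicates 8 and 9 on one side.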

How the results depend on the processing

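The covariates for mesenchyme markers and Y-linked genes, the robust fit, the table without Rn45s, and KO replicate 8 left out together with the Y-linked covariate were chosen after seeing the data. No paired analysis was possible because the genotypes share no replicate numbers.

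All 144 called genes kept their direction under every alternative that gave them a value. Their KO and Het libraries do not overlap, so leaving out 1 library could hardly turn a direction. Of the 27 named genes called, 11 stayed called under all alternatives that gave a value other than the test against a fold of 1.5, and with any 1 library left out (among them Nnat, B3gnt3, G6pc2, Ins1, Npy, Skap1, Cpe, Manf, Creld2 and Sdf2l1), and 16 lost the call when at least 1 library was left out, which leaves fewer samples. Against a fold of 1.5, 9 of these 11 were called, and Manf (adjusted p = 0.104) and Sdf2l1 (0.0725) were not. All 27 were called without KO replicate 8. The counts of called, higher and lower genes, 144, 48 and 96, became 585, 270 and 315 with DESeq2, 500, 196 and 304 by limma-voom with quality weights, 580, 219 and 361 with 1 surrogate variable, 77, 21 and 56 with the acinar covariate, 26, 6 and 20 against a fold of 1.5, 596, 231 and 365 with the mesenchyme covariate, 28, 6 and 22 with the Y-linked covariate, and 135, 39 and 96 with that covariate and KO replicate 8 left out. With 1 library left out they ranged from 29 (without Het replicate 13) to 285 (without KO replicate 8), 3 to 97 and 26 to 188. Fewer samples may add to the lower counts with 1 library left out, although leaving out KO replicate 8 raised the counts. The cause of these shifts was not tested. Over the 144 genes, the Y-linked covariate multiplied log2 fold changes by a median of 0.979 and SEs by 1.18. The 21 called members of the lists became 40 with DESeq2, 48 with quality weights, 56 with the surrogate variable, 54 with the mesenchyme covariate, 7 with the Y-linked covariate, 5 against a fold of 1.5, and 8 to 37 with 1 library left out.

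Neurod1 had a log2 fold change of −3.18 with the Y-linked covariate (adjusted p = 0.0725), and of −3.68 to −3.06 with 1 library left out. The 13 lists called by camera became 0 with an estimated correlation, 3 by fry, 8 with the mesenchyme covariate, 5 without KO replicate 8 with the Y-linked covariate, and 8 to 15 with 1 library left out. By group medians the hormone share differed by −3.71 (exact permutation p = 0.0571) and the acinar share by −0.0386. With 1 library left out the acinar share difference ran from −0.472 to 1.14 and the cell-cycle score difference from −0.895 to −0.447. The cause was not tested.

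These sign changes were of genes not called. Ppy ran from −0.0905 to 0.38 with 1 library left out. Pyy was 0.00884 by total counts, 0.19 with quality weights, 0.0639 without KO replicate 8 with the Y-linked covariate, and −0.24 to 0.0670 with 1 library left out. Ghrl was 0.0285 with quality weights, 0.00723 with the surrogate variable, 0.0189 with the Y-linked covariate, 0.15 when KO replicate 8 was also left out, and −0.55 to 0.0532 with 1 library left out. Cela1 ran from −0.0175 to 0.64. Alas2 was 0.0114 by limma-voom, 0.0222 with the surrogate variable, 0.00562 with the mesenchyme covariate, 0.0194 with the Y-linked covariate, 0.0153 when KO replicate 8 was also left out, and −0.28 to 0.20 with 1 library left out. Among lists, directions turned for the endocrine progenitor genes with the mesenchyme covariate (camera adjusted p = 0.9998), the Y-linked covariate (0.986) and that without KO replicate 8 (0.263), with 0.0462 to 0.658 when 1 library was left out. They turned for the mesenchyme markers with the Y-linked covariate (0.986) and that without KO replicate 8 (0.0806), with 0.0238 to 0.658 for 1 library left out. They turned also for the G1 regulators (0.460 to 0.904) and the acinar-cell markers (0.0283 to 0.662) with 1 library left out. The called list of genes usually silent in beta cells turned without KO replicate 8 with the Y-linked covariate (0.580). The cause was not tested. At 4 libraries per group, 30 of 100 simulated changes of 2-fold were recovered among genes of at least 8 CPM, so small changes can be missed.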

Other observations

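The genes in this part were chosen after their values were seen, and no test of an explanation was run on them. Beyond the fixed list, some other genes of the protein entry, folding and export machinery of the endoplasmic reticulum were lower in KO. Hyou1 (log2 fold change −1.03, edgeR adjusted p = 0.0380), the degradation factors Derl2 (−1.31, adjusted p = 0.0165) and Derl3 (−1.91, adjusted p = 0.0151), the signal peptidase subunit Spcs3 (−1.11), the translocon-associated Ssr4 (−0.77), the oligosaccharyltransferase subunit Rpn2 (−0.64) and Uggt1 (−0.62), which senses unfolded glycoproteins, all fell. Of 19 tested genes named Pdia, Ssr, Spcs, Derl, Sec61 or Rpn outside the fixed list, 5 fell, all among those named above, none rose and 17 had a negative log2 fold change (median −0.57, SD 0.48). Without KO replicate 8, whose removal raised the calls over all genes from 144 to 285, 5 were lower. Their calls without any other library were not counted.

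Other single genes differed as well. The purinergic receptor gene P2ry1 fell from 315 ± 85.9 to 82.0 ± 10.9 CPM (SD, n = 4 each; log2 fold change −1.94, edgeR adjusted p = 0.00437), and Ffar3 (−1.95), Crhr2 (−2.37), the calcium pump gene Atp2a3 (−1.57) and the gastrin gene Gast (−1.49, adjusted p = 0.00983) fell too. The fructose transporter gene Slc2a5 fell from 76.0 ± 3.93 to 15.6 ± 1.92 CPM (−2.29, adjusted p = 0.000154). Enpep (1.58), Cpm (1.33), Slc7a8 (1.499, adjusted p = 0.0165), Slc3a2 (0.64), Slc38a1 (0.86), Adcy1 (1.87), Soat1 (1.30, adjusted p = 0.00303) and Txnip (0.69) rose. Some calls lay near the threshold, with an edgeR adjusted p of 0.0489 for Slc3a2 and 0.0403 for Ffar3. Whether the calls of these single genes held with other libraries than KO replicate 8 left out, or with a covariate, is not given here. Trpm5 had a log2 fold change of −1.75 (adjusted p = 0.195), and of −2.79 without KO replicate 8 (adjusted p = 6.26e-05). Spc25, which lies next to G6pc2 in the reference annotation used here, fell as well (−2.46, adjusted p = 0.0227). The genes of this pair lie on opposite strands and do not overlap in that annotation, and the annotation behind the deposited counts is not given in the sources used here.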
